A study of Homo sapiens with 6 samples.

How the data were processed

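Cells labelled MCF-7, an established human breast cancer cell line, had been transfected with a plasmid for overexpression of RNPC1 or with the vector plasmid, and total RNA taken with Trizol was made into TruSeq libraries and sequenced on a NovaSeq instrument, per the labels' protocols. RNPC1 is an alias of RBM38. There were 3 libraries labelled vector and 3 labelled oeRNPC1, and groups and replicate numbers were taken from the sample titles. The labels state 3 repeats but not whether these were separate cultures, so p-values measure the spread between these libraries, which may be technical. The cell line field counts upward from MCF-7 through the samples, while every sample description names MCF-7, which was used here.

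The authors deposited 1 table per library, each with the same 2004 genes, and each value is a normalised read signal of that library. In these deposited signal columns every value above 0 was a whole multiple of a single step per library (within 0.01 of a step), which is what gene read counts divided by a size factor per library give. The aligner, the counting tool, the annotation and the test the authors used are not given in the sources used here. The deposited tables also hold the authors' group means, the authors' log2 fold changes, and the authors' p-values and adjusted p-values. The authors' deposited log2 fold changes were smaller than the log2 ratio of the deposited group means, with a median ratio of 0.874. The genome build is named mm9, a mouse build, in the submitters' processing notes. The gene identifiers are human: 1995 of the 2004 are human Ensembl identifiers, 1994 of them were found in GENCODE 29, 1993 lay on the same chromosome there, and 1604 (80.4%) shared its start or end, so positions are given as deposited and were set beside GRCh38, the assembly of GENCODE 29. The remaining 9 loci carry names of the authors' own.

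The deposited tables hold only part of the genes. The largest p-value of the authors among the 2004 genes was 0.049959976, so a gene that is not listed had an authors' p-value of 0.05 or more or was not tested. The authors' p-values and adjusted p-values together imply that 10705 genes had been tested. A further 181 listed genes, with mean levels of at most 104.5, carry an adjusted p-value of 1 in the authors' deposited table and were not among those 10705. Values divided by their library's step summed to 3370813 in vector replicate 1 and 5031044 in oeRNPC1 replicate 1, the lowest and highest library, over the listed genes. These sums are not library depths, which are unknown. Relative depth, the inverse of the step, ran from 0.783 in vector replicate 1 to 1.15 in oeRNPC1 replicate 1. Replicates of a group differed by more than counting noise, with chi-square per degree of freedom from 2.54 to 11.3, and none was treated as a duplicate.

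Values were analysed as log2(value + 1) with limma 3.58.1 (limma-trend, empirical Bayes moderation) in R 4.3.3, with group as the only term. A filter on a mean of at least 1 removed no listed gene. The design had planned a count test if the files held counts, and the log-scale test if they held CPM, TPM, RPKM or FPKM. Size-factor normalised values were not named in it, and the log-scale test was chosen for them. Dividing by the step gives whole numbers for the listed genes, but no count test was run on these. P-values were adjusted by the Benjamini-Hochberg method over all 10705 genes tested by the authors, with every unlisted gene taken to rank below the listed ones, and a gene was called at an adjusted p under 0.05. The 181 low genes outside that set received no adjusted p. This adjustment was settled after the tables had been seen, because the listed genes had been selected by the authors' p-values from the same libraries. Fitted p-values are therefore not independent of that selection, and an adjustment over all 2004 listed genes against the same 10705, tried first, is among the alternatives. In simulations of 10705 genes with 1000 changed, with only genes of p under 0.05 kept, adjustment over all tested genes gave 4.24% false calls at a dispersion of 0.001833, the median of listed genes, and 4.14% at 0.003666. Adjustment over the kept genes alone gave 31.6% and 32.0%. A simulation without selection held 2003 genes and was adjusted over these, not over 10705. In it 80% of 50 genes changed 1.2-fold and 100% of those changed 1.4-fold, 1.6-fold or 2-fold were recovered. The simulations drew noise independently at a single dispersion for all genes, and those with selection used limma p-values, not the authors'. The dispersion came from listed genes, which had been selected for differing, so these rates need not hold for the real libraries. Fold changes are on the log2(value + 1) scale, which understates the change of low genes.

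Gene lists were tested with limma's camera, preset correlation 0.01, for the 16 of 27 lists with at least 5 listed members, with Benjamini-Hochberg adjustment over the 16. Camera compared a list with the other listed genes, not with all expressed genes. Counts "adjusted over the list alone" took the number of genes in the list as the number of tests, so that an unlisted member counted as not passing. The lists, the tests and the rule for named genes were fixed before the data were examined. The rule took RBM38, the 10 largest rises and 10 largest falls by fitted fold change among called genes with a symbol, non-overlapping groups and no pseudogene or clone name, all listed members of a list of RBM38 targets in the literature, and up to 4 members with the smallest p of each other list.

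Alternatives were a pseudocount of 0.1, no filter on low values, a mean of at least 5, quantile normalization over the listed genes, the replicate number as a block, each library left out in turn, an adjusted p under 0.01, a 2-fold minimum, limma's treat against a 1.2-fold change, camera with an estimated correlation, and fry. Added after seeing the data were a mean of at least 100, adjustment over the listed genes alone, and removal of a loess trend (span 0.75) of fold change on transcript length. Transcript length, here and below, is the gene length the authors deposited. How it was derived is not given, and it need not be the length of the mRNA present. Alternatives planned for count tables were not run. For 3′ UTR sequences, 1 coding transcript per gene was taken from GENCODE 29 (the principal isoform, then the longest), and UTRs under 200 nt were left out. Observed counts of a pentamer were divided by the count expected from the UTR's base composition, with Python 3.11.15, and differences were taken again within 5 classes of transcript or UTR length, with permutation inside the classes.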

Results

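The series holds mRNA profiles of cells labelled MCF-7, the name of an estrogen receptor-positive human breast cancer line, with and without overexpression of RNPC1, the RNA-binding protein encoded by RBM38. The levels of EGFR and COL1A1 given at the end are unusual for that line, ESR1 was not among the listed genes, and the identity of the cells was not tested here. Of the 6 libraries, 3 came from cells given the vector plasmid (vector) and 3 from cells given the overexpression plasmid (oeRNPC1). The deposited values are size-factor normalised read signals for 2004 genes, those with an authors' p-value under 0.05, so the levels below describe a selected set and not the whole transcriptome. Divided by the step of its library, which is what 1 read would be worth, the values of these genes summed to between 3370813 and 5031044 per library. Full library depth is unknown.

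The first measurement was the level of the overexpressed gene itself. RBM38 (ENSG00000132819, chromosome 20, 57391396 to 57409333, plus strand) stood at 340.0 ± 17.3 normalised counts in the vector libraries and 14786 ± 954 in the oeRNPC1 libraries (SD, n = 3 each). The values were 320.4, 346.1 and 353.4 in vector replicates 1, 2 and 3, against 14699.6, 15781 and 13879 in oeRNPC1 replicates 1, 2 and 3. The fitted log2 fold change was 5.44 (SE 0.060), a 43.3-fold rise, with a limma adjusted p of 4.59e-18. Reads from the plasmid and from the chromosomal gene are not separated in a gene-level value. The authors' deposited table gives a log2 fold change of 4.81 for this gene.

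The second comparison asked which other genes differed between cells with and without RNPC1 overexpression. Outside RBM38 the changes were small. Of the called genes that rose, complement component C3 and the Notch-modifying glycosyltransferase LFNG changed most. Among the called genes with a symbol that fell, the calcium-activated chloride channel ANO2 and the transcriptional regulator CREBRF led. In total 301 genes were higher and 204 lower in oeRNPC1 (limma, Benjamini-Hochberg adjusted p under 0.05 over 10705 genes). The median size of a called change was 1.22-fold, and 455 of the 505 called genes (90.1%) had an absolute log2 fold change under 0.5. After quantile normalization over the listed genes the calls were 154 higher and 181 lower, so the share of calls that were higher moved from 59.6% to 46.0%. Leaving out 1 library moved the counts to 89 higher and 32 lower without vector replicate 2, 52 and 25 without vector replicate 3, 89 and 63 without oeRNPC1 replicate 1, 178 and 97 without oeRNPC1 replicate 2, and 467 and 366 without oeRNPC1 replicate 3. Such fits have 1 library fewer, so a call can be lost with or without a smaller fold change. ELAVL1 had a log2 fold change of 0.3257 without vector replicate 3, where it was not called, against 0.3252 with all libraries. MDM2 had one of -0.26 without oeRNPC1 replicate 2, where it was not called, against -0.36. The authors' deposited table has 563 genes at an adjusted p-value under 0.05, 320 higher and 243 lower, of which 478 were also called here.

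Among the 10 largest rises, C3 (chromosome 19, 6677704 to 6730562) went from 676 ± 139 to 1321 ± 186 normalised counts, a log2 fold change of 0.97 (SE 0.12, adjusted p = 0.00055). LFNG went from 165 ± 23.7 to 287 ± 4.39 (log2 fold change 0.80, SE 0.11, adjusted p = 0.00146). The chemokine CCL5 rose 1.62-fold, from 1546 ± 215 to 2525 ± 531, and the ubiquitin ligase RNF38 (chromosome 9, 36336396 to 36487548) rose 1.61-fold, from 917 ± 55.5 to 1481 ± 38.4 (adjusted p = 3.18e-05). The other 6 were PLAAT4, C4B, OAS2, TMOD1, OASL and NCF2, with log2 fold changes from 0.62 to 0.68. C4B shares near-identical sequence with C4A, so its level is uncertain. TMOD1, with an adjusted p of 0.0476, was not called after quantile normalization (adjusted p = 0.222), with a pseudocount of 0.1 (adjusted p = 0.0538) or with a mean of at least 100 (adjusted p = 0.0515), and without 1 library it was called only where oeRNPC1 replicate 3 was left out (adjusted p from 0.0719 to 0.214 in the other 5 fits). OAS2 was not called after quantile normalization (adjusted p = 0.147) or without vector replicate 2, vector replicate 3, oeRNPC1 replicate 1 or oeRNPC1 replicate 2 (adjusted p = 0.07, 0.19, 0.161 and 0.123). CCL5, PLAAT4, C4B and NCF2 were not called without vector replicate 3 (adjusted p from 0.0787 to 0.0921) or oeRNPC1 replicate 1 (adjusted p from 0.0601 to 0.0749), nor PLAAT4 and C4B without vector replicate 2 (adjusted p = 0.066 and 0.0747). Quantile normalization also ended the call of C4B (adjusted p = 0.0512), and removal of the length trend those of PLAAT4 (adjusted p = 0.0646) and TMOD1 (adjusted p = 0.0724). With the replicate number as a block TMOD1 was not called either (adjusted p = 0.108). Of the 10, the antiviral enzyme family member OASL was the most abundant, at 8350 ± 1191 against 13112 ± 2060.

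**Figure D1:**
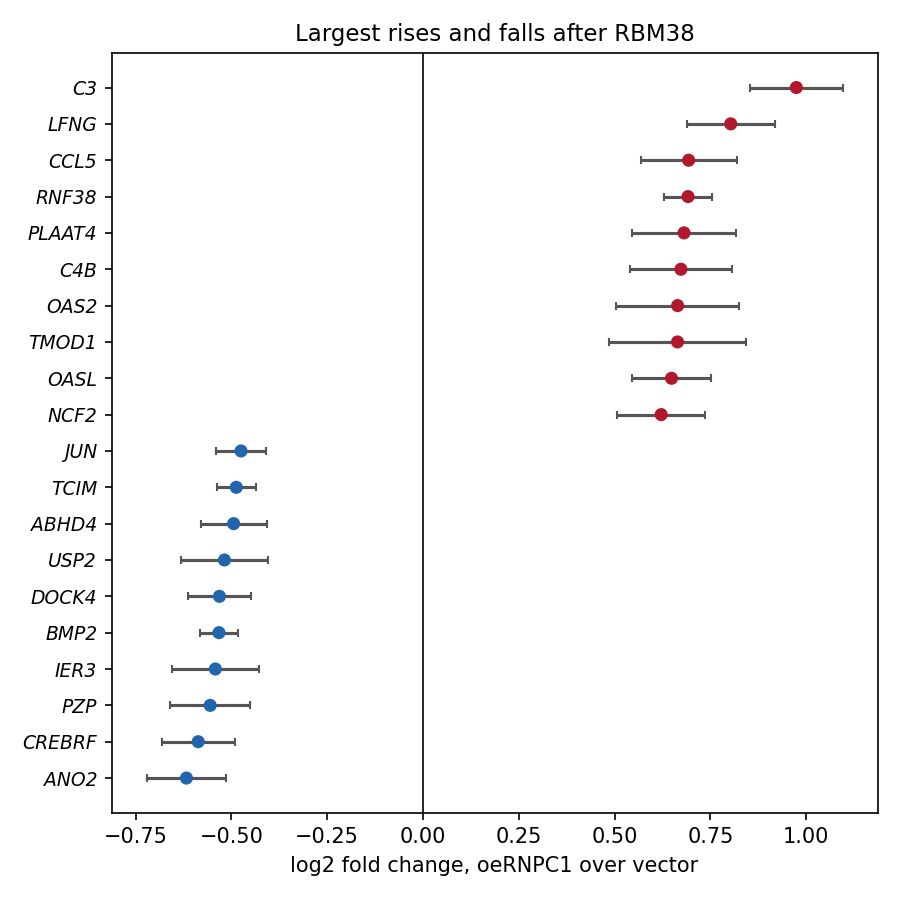
The 10 largest rises and 10 largest falls chosen by the fixed rule, RBM38 left out. The x axis is the fitted log2 fold change of oeRNPC1 over vector on the log2(value + 1) scale, points are genes (red higher, blue lower) and bars are 1 standard error; the rises run from 0.62 (NCF2) to 0.97 (C3) and the falls from -0.47 (JUN) to -0.62 (ANO2).

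Among the 10 largest falls, ANO2 went from 352 ± 21.5 to 230.0 ± 25.1 normalised counts (log2 fold change -0.62, SE 0.10, adjusted p = 0.00416), and CREBRF from 384 ± 26.1 to 255 ± 15.8 (log2 fold change -0.59, SE 0.095, adjusted p = 0.00342). The secreted growth factor BMP2 (chromosome 20, 6767686 to 6780246) was the most abundant, at 3447 ± 131 in vector and 2382 ± 47.9 in oeRNPC1 (log2 fold change -0.53, SE 0.050, adjusted p = 3.18e-05). The gene TCIM went from 2662 ± 59.5 to 1899 ± 34.9, with an adjusted p of 9.25e-05. The transcription factor JUN and the early response gene IER3 were also among them, at log2 fold changes of -0.47 and -0.54. PZP, DOCK4, USP2 and ABHD4 made up the rest, with log2 fold changes from -0.49 to -0.56. IER3 and USP2 were not called without vector replicate 2, vector replicate 3, oeRNPC1 replicate 1 or oeRNPC1 replicate 2 (adjusted p from 0.0538 to 0.134), nor PZP without vector replicate 2 (adjusted p = 0.0706) or oeRNPC1 replicate 1 (adjusted p = 0.0515).

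Interferon-stimulated genes had the highest median of the 16 lists with at least 5 listed members. Of the list's 38 genes 20 were listed, all 20 had higher values in oeRNPC1 (19 with the length trend removed), and 11 rose at the adjusted threshold over all genes tested; 16 did so adjusted over the list alone. The antiviral proteins IFIT1 and IFIT2 rose from 2881 ± 174 to 4236 ± 525 and from 8987 ± 790 to 12664 ± 1353 normalised counts, 1.46-fold and 1.41-fold. The ISG15 ligase HERC5 rose 1.34-fold, from 1744 ± 4.34 to 2341 ± 140, with an adjusted p of 0.000877. The median log2 fold change of the 20 members was 0.37, and the list stood above the other listed genes with a camera adjusted p of 0.00014, against an adjusted p = 0.423 with an estimated correlation. The number called was 6, 4, 6 and 7 without vector replicate 2, vector replicate 3, oeRNPC1 replicate 1 and oeRNPC1 replicate 2, 18 without oeRNPC1 replicate 3, and 6 after quantile normalization.

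Immediate early genes lay mostly below the vector level. Of 25 genes 12 were listed, of which 9 fell and 2 rose at the adjusted threshold, and the same numbers passed adjusted over the list alone. JUN fell from 1822 ± 72.0 to 1313 ± 104.6 normalised counts, the stress-induced factor ATF3 from 2299 ± 33.9 to 1788 ± 48.0, and the matricellular protein gene CCN1 from 5968 ± 310 to 4886 ± 70.2. The nuclear receptor gene NR4A1 fell from 1852 ± 33.2 to 1461 ± 161. The 2 that rose, JUNB and JUND, were named after their values were seen and had log2 fold changes of 0.28 and 0.27, or 0.11 each and no call with the length trend removed. JUNB was also not called without vector replicate 2 or vector replicate 3 (adjusted p = 0.079 and 0.0694), nor JUND after quantile normalization (adjusted p = 0.0808) or without any 1 library but oeRNPC1 replicate 3 (adjusted p from 0.0713 to 0.168). With the replicate number as a block JUND was not called (adjusted p = 0.0687). NR4A1 was not called without vector replicate 2, vector replicate 3 or oeRNPC1 replicate 1 (adjusted p from 0.0721 to 0.0796). The median log2 fold change was -0.31, with a camera adjusted p of 0.0103 and an adjusted p = 0.342 with an estimated correlation. The number called, 11 with all libraries, was 3 without vector replicate 2 or vector replicate 3, 4 without oeRNPC1 replicate 1 and 7 without oeRNPC1 replicate 2.

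Genes of the unfolded protein and integrated stress response were lower on balance. Of 29 genes 18 were listed and 15 of these had lower values (14 with the length trend removed); 6 fell and 2 rose at the adjusted threshold, and adjusted over the list alone 15 fell and 3 rose. The endoplasmic reticulum chaperone HSPA5 fell from 28849.6 ± 47.0 to 23949 ± 195 normalised counts (log2 fold change -0.27, SE 0.043, adjusted p = 0.00311). The phosphatase subunit PPP1R15A fell from 1286 ± 33.8 to 1032 ± 79.0. In the other direction, the mTORC1 inhibitor DDIT4 rose from 8759 ± 137 to 12299 ± 1065, a log2 fold change of 0.49 with an adjusted p of 0.000304. The median log2 fold change was -0.21, with a camera adjusted p of 0.0141 and an adjusted p = 0.342 with an estimated correlation. HSPA5 was not called without vector replicate 3 (adjusted p = 0.051), nor PPP1R15A without vector replicate 2, vector replicate 3 or oeRNPC1 replicate 1 (adjusted p from 0.0783 to 0.0787). The number called, 8 with all libraries, was 3, 2, 3 and 5 without vector replicate 2, vector replicate 3, oeRNPC1 replicate 1 and oeRNPC1 replicate 2.

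RBM38 is itself a transcriptional target of p53, and MDM2, GDF15 and other p53 targets were among the fixed lists. Of 32 p53 target genes 8 were listed, all 8 with lower values in oeRNPC1; 4 fell at the adjusted threshold and 6 adjusted over the list alone. These were the p53 ubiquitin ligase MDM2, from 2161 ± 167 to 1693 ± 190, the secreted factor GDF15, from 2027 ± 268 to 1515 ± 162, GADD45A, from 2103 ± 114 to 1664 ± 171, and BTG2, from 422 ± 18.2 to 327 ± 28.02 normalised counts. Their log2 fold changes lay between -0.34 and -0.42. The median over the 8 was -0.35, with a camera adjusted p of 0.0103 and an adjusted p = 0.342 with an estimated correlation. The number called was 0 without vector replicate 2, vector replicate 3 or oeRNPC1 replicate 1, and 2 without oeRNPC1 replicate 2, where MDM2 and BTG2 were not called (adjusted p = 0.0538 and 0.0767). BTG2 was also not called without vector replicate 1 (adjusted p = 0.0684) or with the replicate number as a block (adjusted p = 0.0568).

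**Figure D2:**
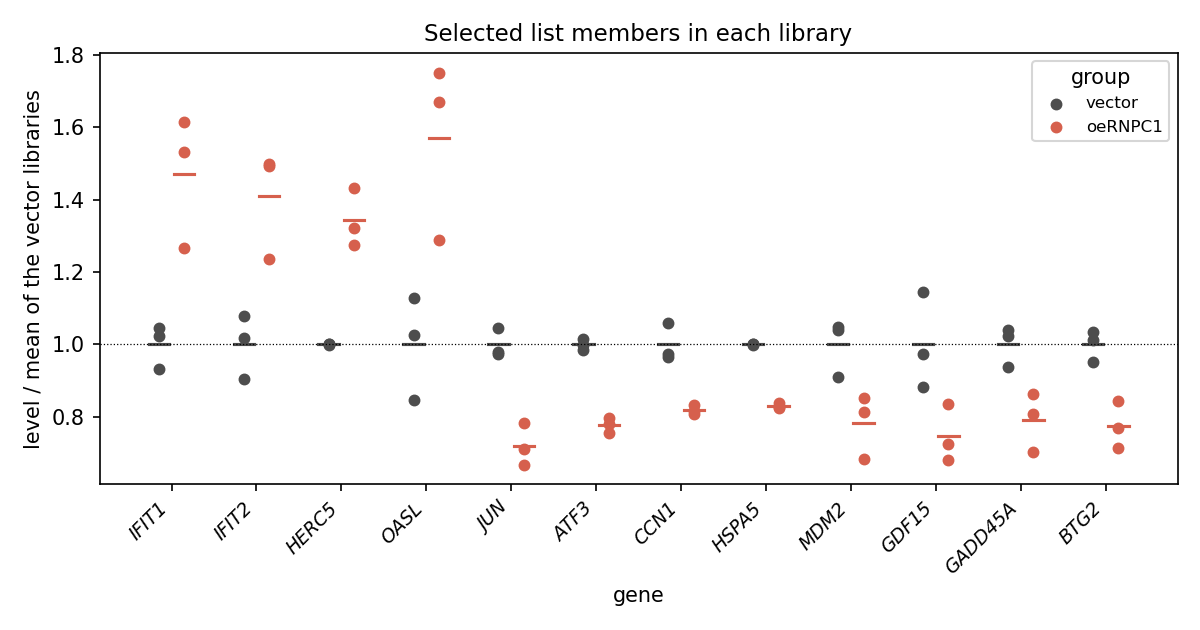
Levels of 12 named members of the interferon, immediate early, stress response and p53 lists in each library, divided by the mean of the 3 vector libraries. The x axis is the gene, the y axis is that ratio, points are libraries (grey vector, red oeRNPC1) and short lines are group means; IFIT1 lies between 1.27 and 1.61 and JUN between 0.668 and 0.782 in the oeRNPC1 libraries.

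Of 15 genes on the list of RBM38 targets in the literature, 4 were listed, too few for a set test. ELAVL1, which encodes the mRNA-stabilising protein HuR, rose from 1813 ± 2.58 to 2275 ± 134 normalised counts (log2 fold change 0.33, SE 0.056, adjusted p = 0.0046). MDM2 and GDF15 fell, as given for the p53 targets, and PTEN stood at 1909 ± 112 against 1659.9 ± 99.1 (adjusted p = 0.0803). Adjusted over the list alone 1 rose and 3 fell. Among mRNA decay and ARE-binding factors 4 of 32 were listed. ELAVL1 and the GU-binding protein CELF1, from 5005 ± 231 to 6004 ± 136, rose, poly(A)-binding protein PABPC1 fell from 22977 ± 107 to 19600.4 ± 1241, and CNOT7 had an adjusted p of 0.101. Adjusted over the list alone 2 of these rose and 1 fell. ELAVL1 and CELF1 were not called without vector replicate 3 (adjusted p = 0.0519 and 0.0642). Their log2 fold changes in that fit were 0.33 and 0.27, against 0.33 and 0.26 with all libraries. PABPC1 was not called without vector replicate 2, vector replicate 3 or oeRNPC1 replicate 2 (adjusted p = 0.123, 0.133 and 0.0536), and with the length trend removed its log2 fold change went from -0.23 to -0.15 (adjusted p = 0.137).

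Cell cycle genes had slightly higher values in oeRNPC1. Of 30 G2/M and mitosis genes 11 were listed, all with higher values (9 after quantile normalization and 10 with the length trend removed), and 3 rose, 1 after quantile normalization and 4 adjusted over the list alone. The survivin gene BIRC5 rose 1.22-fold, from 2318 ± 18.2 to 2834 ± 58.4 normalised counts, and the mitotic kinase gene AURKB had a log2 fold change of 0.26 (adjusted p = 0.0431). AURKB was not called after quantile normalization (adjusted p = 0.0788) or without vector replicate 2, vector replicate 3, oeRNPC1 replicate 1 or oeRNPC1 replicate 2 (adjusted p from 0.119 to 0.231), and its log2 fold change was 0.13 with the length trend removed (adjusted p = 0.719). The replicate number as a block ended its call too (adjusted p = 0.0558). TOP2A rose 1.14-fold, but had a log2 fold change of -0.0025 after quantile normalization, and it was not called without vector replicate 1, 2 or 3 or oeRNPC1 replicate 1 (adjusted p from 0.0702 to 0.168). Of 30 G1/S and DNA replication genes 11 were listed, 10 with higher values (9 with the length trend removed), and 3 rose (UNG, E2F1 and FEN1, at 1.24-fold, 1.25-fold and 1.13-fold), 5 adjusted over the list alone; CCND1 had a log2 fold change of -0.14 and an adjusted p of 0.205. With the length trend removed none of UNG, E2F1 and FEN1 was called, and their log2 fold changes went from 0.32, 0.32 and 0.17 to 0.20, 0.21 and 0.035. E2F1 and FEN1 were also not called after quantile normalization (adjusted p = 0.052 and 0.0584) or without vector replicate 2, vector replicate 3, oeRNPC1 replicate 1 or oeRNPC1 replicate 2 (adjusted p from 0.0712 to 0.236), nor UNG without vector replicate 3 (adjusted p = 0.0654). FEN1 was not called with a pseudocount of 0.1 (adjusted p = 0.0505) or a mean of at least 100 (adjusted p = 0.0513) either. The camera adjusted p was 0.0194 for G2/M and 0.046 for G1/S, with an adjusted p = 0.342 with an estimated correlation for both, and 0.0855 and 0.239 with the length trend removed. The number called ran from 1 to 4 for G2/M and from 0 to 5 for G1/S with 1 library left out; both were lowest without vector replicate 3, and G2/M was as low without vector replicate 2 or oeRNPC1 replicate 1. The G1/S set did not pass without vector replicate 2 (adjusted p = 0.0854) or without oeRNPC1 replicate 1 (adjusted p = 0.0504).

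Of 20 heat shock and chaperone genes 8 were listed, all with higher values (7 of them after quantile normalization or with the length trend removed), and 3 rose, 4 adjusted over the list alone. HSP90AA1 rose from 21122 ± 230 to 24775 ± 590 normalised counts (1.17-fold, adjusted p = 0.00865). HSPA1A and HSPA1B rose 1.28-fold and 1.24-fold, and these 2 near-identical genes share reads, so how the rise divides between them is uncertain. After quantile normalization the log2 fold change of HSPA1A went from 0.36 to 0.13 (adjusted p = 0.125), and with the length trend removed it was 0.23 (called) and that of HSPA1B went from 0.31 to 0.19 (adjusted p = 0.101). Without vector replicate 3 HSPA1B and HSP90AA1 were not called (adjusted p = 0.0688 and 0.0787), nor was HSP90AA1 without vector replicate 2 (adjusted p = 0.094). The camera adjusted p was 0.0194, with an adjusted p = 0.342 with an estimated correlation and 0.113 with the length trend removed, and the number called ran from 1 without vector replicate 3 to 5 without oeRNPC1 replicate 3. YAP/TEAD targets had 5 of 22 genes listed, all with lower values, of which CCN1 fell; 3 passed adjusted over the list alone, the camera adjusted p was 0.0385, and it was 0.342 with an estimated correlation. The YAP/TEAD set passed neither without vector replicate 1 (adjusted p = 0.054) nor without oeRNPC1 replicate 3 (adjusted p = 0.0533).

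**Figure D3:**
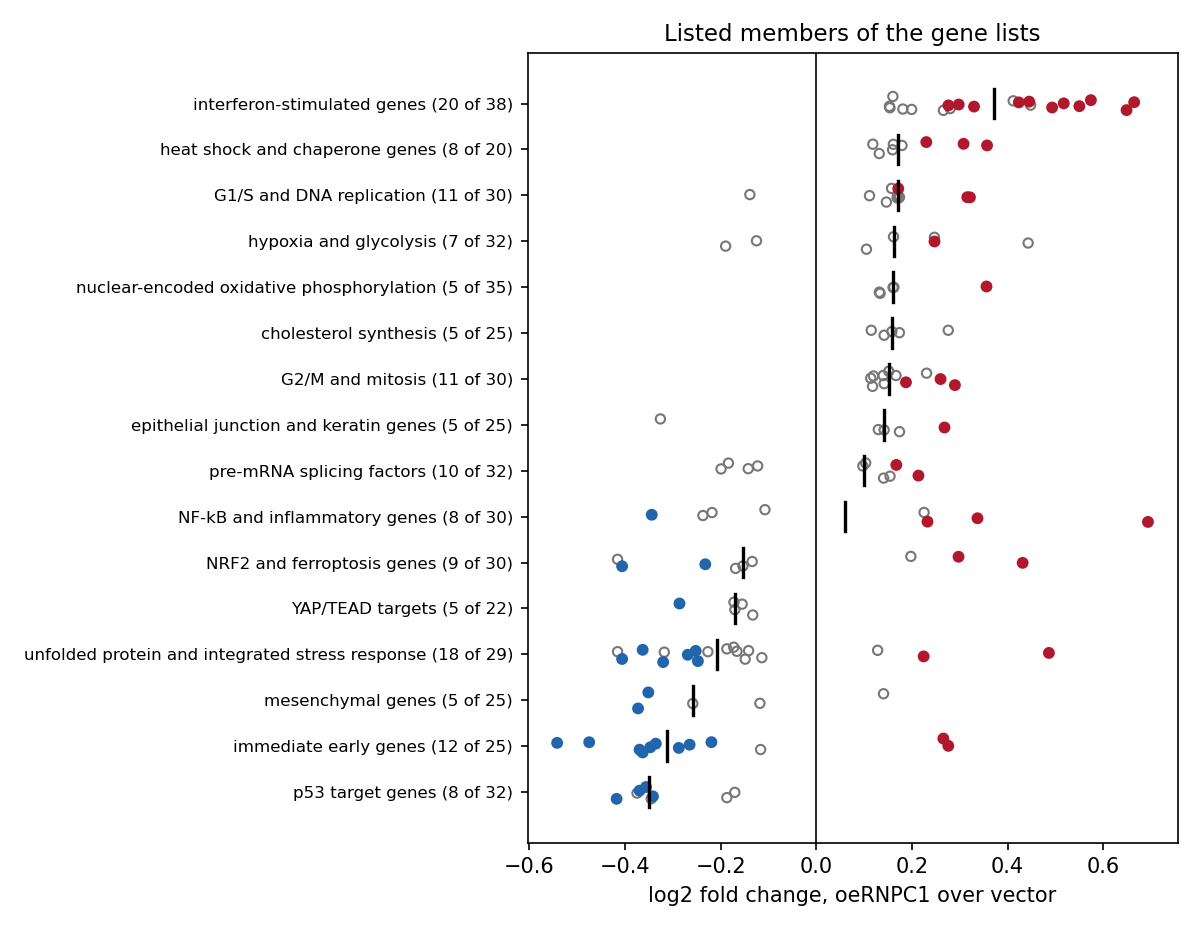
Fitted log2 fold changes of the listed members of the 16 lists with at least 5 listed members, with listed members and list size in brackets. The x axis is the log2 fold change of oeRNPC1 over vector, filled points passed the adjusted threshold (red higher, blue lower), open points did not, and black lines are list medians; the medians run from -0.35 (p53 target genes) to 0.37 (interferon-stimulated genes).

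The other 8 lists tested did not pass. NF-kB and inflammatory genes were split, with 4 of 8 listed members higher and 4 lower: SOD2 and CCL5 rose 1.26-fold and 1.62-fold, TNFAIP2 rose 1.17-fold, and IL6 fell from 1071 ± 67.3 to 843 ± 39.3 normalised counts (camera adjusted p = 0.842). TNFAIP2 was not called after quantile normalization (adjusted p = 0.0745), with the length trend removed (adjusted p = 0.0535) or without any 1 library but oeRNPC1 replicate 3 (adjusted p from 0.0683 to 0.164), nor IL6 without vector replicate 2 (adjusted p = 0.0894), and SOD2 had a log2 fold change of 0.51 with the length trend removed, against 0.34. CCL5 was not called without vector replicate 3 or oeRNPC1 replicate 1, as given above. Of 5 listed mesenchymal genes COL1A1 fell from 8601 ± 146 to 6646 ± 267 and THBS1 from 786 ± 19.0 to 617 ± 47.4, and the list's adjusted p was 0.0824, against 0.0494 without oeRNPC1 replicate 2 and 0.0331 with the length trend removed. THBS1 was not called without vector replicate 2, vector replicate 3, oeRNPC1 replicate 1 or oeRNPC1 replicate 2 (adjusted p from 0.0502 to 0.105). Of 5 listed epithelial junction and keratin genes KRT18 rose, with a log2 fold change of 0.27 (camera adjusted p = 0.329); it was 0.18 and not called with the length trend removed (adjusted p = 0.117), and the same 4 libraries left out in turn ended the call (adjusted p from 0.0684 to 0.162).

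NRF2 and ferroptosis genes had 2 of 9 rise, ACSL4 and HMOX1, and 2 fall, TFRC and SLC7A11 (camera adjusted p = 0.329). The number called ran from 0 without vector replicate 3 or oeRNPC1 replicate 1 to 7 without oeRNPC1 replicate 3. SLC7A11, whose groups overlap (adjusted p = 0.0466), and HMOX1 were not called after quantile normalization (adjusted p = 0.131 and 0.0555) or with the length trend removed (adjusted p = 0.132 and 0.0798), nor without vector replicate 2, vector replicate 3, oeRNPC1 replicate 1 or oeRNPC1 replicate 2 (adjusted p from 0.177 to 0.293 and from 0.0559 to 0.0761). SLC7A11 was also not called with a pseudocount of 0.1 (adjusted p = 0.0535). TFRC was not called without vector replicate 2, vector replicate 3 or oeRNPC1 replicate 1 (adjusted p from 0.0616 to 0.128), nor ACSL4 without the last 2 of these (adjusted p = 0.0939 and 0.0643). HK2 rose 1.19-fold among 7 listed hypoxia and glycolysis genes (0.329) and NDUFS2 rose 1.28-fold among 5 listed oxidative phosphorylation genes (0.121). HK2 was not called without vector replicate 2, vector replicate 3 or oeRNPC1 replicate 1 (adjusted p from 0.0568 to 0.0673), nor NDUFS2 without vector replicate 3 (adjusted p = 0.0688). Of 5 listed cholesterol synthesis genes 0 were called by limma (0.136 for the list). All 5 had an unadjusted p under 0.05, as did 1994 of the 2004 listed genes. HNRNPM and HNRNPK rose among 10 listed splicing factors (0.716), whose median turned from 0.10 to -0.0091 after quantile normalization. HNRNPK went from a log2 fold change of 0.17 to one of 0.067 there (adjusted p = 0.537) and was not called with the length trend removed (adjusted p = 0.0628). Neither of the pair was called without vector replicate 2, vector replicate 3, oeRNPC1 replicate 1 or oeRNPC1 replicate 2 (adjusted p from 0.0607 to 0.231). Adjusted over the list alone, the members passing were 6 for NF-kB, 3 for mesenchymal, 1 for epithelial, 7 for NRF2, 3 for hypoxia, 1 for oxidative phosphorylation, 0 for cholesterol synthesis and 4 for splicing.

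Of the lists too small to test, 4 of 30 estrogen receptor targets were listed, and STC2 fell from 1481 ± 24.1 to 1171 ± 48.0 normalised counts (adjusted p = 0.0046, and 0.0519 without vector replicate 3). The number of cell type markers listed does not show how many were expressed, since the table holds only genes with an authors' p-value under 0.05. COL1A1 fell, and MFAP5 and DCN had adjusted p-values of 0.151 and 0.12, among 3 of 12 fibroblast markers. EGFR fell from 6038 ± 32.1 to 4944 ± 301 among 2 of 12 basal mammary markers, and the other, ITGB4, stood at 69.6 ± 9.27 against 137 ± 10.4 with no adjusted p. EGFR had a log2 fold change of -0.29, which was -0.17 and not called with the length trend removed (adjusted p = 0.0732), and it was not called without vector replicate 3 (adjusted p = 0.0603). CD19, at 21.9 ± 6.43 against 39.7 ± 2.22 and with no adjusted p, was the only one of 14 leukocyte markers listed, and 0 of 10 endothelial markers were. From the mitochondrially encoded mRNAs MT-ND4L was listed (adjusted p = 0.172), and from 40 cytosolic ribosomal protein genes RPS23 (adjusted p = 0.115). The lists of replication-dependent histones and of lysosome and autophagy genes had 0 listed members. Adjusted over the list alone 1 estrogen receptor target, 1 fibroblast marker, 2 basal markers and 1 leukocyte marker passed.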

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

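The mean of at least 100, the adjustment over the listed genes alone and the removal of the length trend were chosen after the data were seen. RBM38 kept its rise in every fit, at a log2 fold change from 5.33 to 5.48, and with 1 library left out from 5.39 to 5.48. The main counts were 301 genes higher and 204 lower. They changed to 154 higher after quantile normalization, 94 higher and 43 lower at an adjusted p under 0.01, 6 higher and 1 lower (the unannotated locus on chromosome 19) with treat against a 1.2-fold change, and 1 higher (RBM38) and 1 lower (that locus) with a 2-fold minimum. Adjustment over the listed genes alone gave 964 higher and 849 lower, because fewer tests were counted, with 31.6% false calls in the simulation. With 1 library left out the counts ran from 52 to 467 higher and from 25 to 366 lower. Without the filter on low values, and with all 2004 listed genes in the adjustment, 387 were higher and 267 lower. With the replicate number as a block 231 genes were higher and 150 lower, and 356 of the 505 calls were shared. After quantile normalization 281 of the 505 were shared. With the length trend removed 354 genes were higher and 211 lower, 298 of the 505 calls were shared, and 7 called genes changed sign. Same-numbered libraries had correlations of deviations of 0.066, -0.27 and 0.40, and not every library correlated best with its own number. Deviations from a group mean sum to 0 over its 3 libraries, so these values neither show nor exclude a pairing by number. Of the 16 gene lists 4 were higher and 4 lower. With an estimated correlation 0 were higher and 0 lower, with fry 8 were higher and 5 lower, and with the length trend removed 1 was higher and 5 lower. Fry asks only whether the members of a list move one way, and these members had been selected for differing. With 1 library left out 3 to 4 lists were higher and 3 to 5 lower. Over 14 fits, 95 named genes kept their side of the threshold and direction in 1098 values, lost a call in 150, gained one in 78 and turned direction or went to 0 in 3. These 3 were TOP2A (-0.0025) and HSP90AB1 (0 at 4 decimals, adjusted p = 1) after quantile normalization and MT-ND4L (-0.29) with the length trend removed, and the splicing factor list turned to a median of -0.0091 after quantile normalization; the cause was not tested. Quantile normalization was made over listed genes only, which had been selected for differing, and moved the median log2 fold change of listed genes from 0.13 to 0.12. The alternatives planned for count tables (other size factors, other count tests and count filters) were not run. The 181 listed genes with means of at most 104.5 were outside the 10705 genes counted in the adjustment and received no adjusted p.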

Other observations

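Several gene families not among the fixed lists were picked after their members' directions were seen, so counts and no tests of direction are given for them, and the tests of transcript length and of pentamer order in this part were also chosen after the data were seen. Of the 2003 listed genes other than RBM38, 1055 had higher and 948 lower values. Cytosolic aminoacyl-tRNA synthetase genes were mostly lower in oeRNPC1: of 20 genes 12 were listed, 11 with lower values (12 after quantile normalization and 10 with the length trend removed), and 6 fell. GARS1 had a log2 fold change of -0.31 (SE 0.048, adjusted p = 0.00243) and YARS1 one of -0.22 (SE 0.047, adjusted p = 0.0166), while WARS1, which interferon is known to induce, stood at 0.16 (adjusted p = 0.0869). Of 49 ribosome biogenesis factors 20 were listed, 19 with lower values, and 11 fell, 7 after quantile normalization, among them UTP20 at -0.29 and URB1 at -0.25. Of 6 listed laminin and collagen genes 4 fell, COL1A1, LAMA1, LAMA5 and LAMA3. With the length trend removed 4 synthetase genes, 6 ribosome biogenesis factors and 1 of the laminin and collagen genes, COL1A1, were called lower, and GARS1, YARS1, UTP20, URB1, LAMA1, LAMA5 and LAMA3 were not. Without vector replicate 1, vector replicate 2, vector replicate 3, oeRNPC1 replicate 1 and oeRNPC1 replicate 2 the synthetase genes called lower were 2, 1, 1, 2 and 3, the ribosome biogenesis factors 8, 0, 0, 4 and 4, and the laminin and collagen genes 4, 1, 1, 2 and 4.

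Among genes of innate sensing 9 of 20 were listed and 6 rose, including the antiviral RNA-binding protein gene ZC3HAV1 at 0.52 (SE 0.059, adjusted p = 0.000272) and the mitochondrial adaptor gene MAVS at 0.22 (adjusted p = 0.0234). Of 5 listed JAK and STAT genes STAT5A, STAT5B and STAT2 rose, with log2 fold changes of 0.47, 0.35 and 0.28, JAK1 fell, with one of -0.20 (adjusted p = 0.0331), and STAT3 had an adjusted p of 0.0869. With the length trend removed JAK1 was at -0.081 and not called. DHX58 and IFIH1, among the innate sensing genes that rose, and STAT2 are also on the interferon-stimulated list, so these families are not independent of it. The innate sensing genes called higher were 2 after quantile normalization and 1 without vector replicate 2, vector replicate 3 or oeRNPC1 replicate 1, where MAVS was not called. STAT2 was not called after quantile normalization or without vector replicate 2, vector replicate 3, oeRNPC1 replicate 1 or oeRNPC1 replicate 2, nor JAK1 without vector replicate 2, vector replicate 3 or oeRNPC1 replicate 2, nor STAT5B without vector replicate 3. Of 117 annotated pseudogenes 97 had higher values, with 25 called higher and 2 lower, or 8 and 3 after quantile normalization; their reads are hard to tell from those of the parent genes, and with the length trend removed 67 had higher values, with 3 called higher and 6 lower. Of 136 genes with a transcription factor family, as deposited, 54 had higher and 82 lower values, while 22 were called higher and 18 lower, or 10 and 18 after quantile normalization and 19 and 25 with the length trend removed. Of 76 lncRNA genes 29 had higher and 47 lower values, with 4 called higher and 2 lower, or 1 and 4 after quantile normalization and 8 and 5 with the length trend removed. Without vector replicate 3 and without oeRNPC1 replicate 3 the calls were 4 higher and 1 lower and 46 and 5 for pseudogenes, 4 and 4 and 26 and 40 for transcription factors, and 1 and 0 and 8 and 4 for lncRNA genes. HMGB2 and OTUD1 had 2 of the smallest adjusted p-values, 3.17e-05 and 2.79e-05, with log2 fold changes of 0.61 and 0.60. One called gene besides RBM38 changed more than 2-fold, a locus named by the authors at chromosome 19, 3501529 to 3506213 (plus strand), which went from 157 ± 28.3 to 61.8 ± 13.1 normalised counts (adjusted p = 0.000877).

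The 10 possible splits of the 6 libraries are too few for a share under 0.05. The real split called 505 genes and the highest of the others 7, so of the 10 splits only 1, the real one itself, gave as many. The listed genes had been selected for differing between the real groups, which alone lowers the count in other splits. Along the axis between the group means of listed genes above a mean of 100, vector replicate 1 lay at 0.10 and oeRNPC1 replicate 3 at 0.81, where the vector mean is 0 by construction.

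The first pattern weighed was the higher level of listed interferon-stimulated genes, with a median log2 fold change of 0.37 (SD 0.17 over the 20 listed of 38 genes). With the trend of fold change on transcript length removed the median was 0.37, after quantile normalization it was 0.29, and the lowest value with 1 library left out was 0.31. The length-corrected and quantile-normalized medians each keep more than 0.5 of the main median. The length-corrected value argues against transcript length as the whole source. The quantile-normalized value cannot decide on library scaling, since that fit used listed genes only, which had been selected for differing. It moved their median log2 fold change only from 0.13 to 0.12. The leave-one-out median cannot count against a single library. The members were listed for an authors' p under 0.05 over the same 6 libraries, so a change carried by 1 library would rarely be listed. Transfected plasmid itself is known to induce such genes, and the amount of plasmid taken up per group was not measured here, so a response to RBM38 may be at work or one to a difference between the plasmids.

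The second pattern was the lower level of listed immediate early, stress response and p53 target genes, with a median of -0.26 (SD 0.23 over 35 genes). Of the lists' 25, 29 and 32 genes only 12, 18 and 8 were listed, so the median covers members selected for differing. The median was -0.29 with the length trend removed and -0.28 after quantile normalization. The first value argues against transcript length as the whole source. The second cannot decide on library scaling, for the reason given for the interferon-stimulated genes. In the leave-one-out fit nearest to 0 the median was -0.23. That value cannot count against a single library, for the reason given for the interferon-stimulated genes. The sets share members such as ATF3 and BTG2 and are not independent. Among other stress genes, all 8 listed heat shock and chaperone genes had higher values (7 after quantile normalization or with the length trend removed), 3 of them called (adjusted p = 0.342 for the list with an estimated correlation), and DDIT4 rose, with a log2 fold change of 0.49. A response to RBM38 and a difference in handling both stay open, since the labels give no harvest or batch.

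The third pattern was that genes that fell have longer deposited gene lengths, called transcript length here, which need not be the length of the mRNA present. Called genes that fell had a median length of 7533 nt and those that rose 4763 nt, and over the 2003 listed genes other than RBM38 Spearman's rho between log2 fold change and length was -0.29 across genes, which are not independent replicates. Over protein-coding genes alone rho was -0.30, and with mean level held constant -0.27, which argues against pseudogenes or expression level as the source. The slope of log2 level on log2 length was 0.030, 0.045 and 0.048 in the vector libraries and -0.021, -0.081 and -0.021 in the oeRNPC1 libraries. The gap between the nearest libraries of the groups, vector replicate 1 and oeRNPC1 replicate 3, was 0.051. A difference in RNA integrity or library yield by length could give this gap, as could a biological change. The 2 cannot be told apart with library and group confounded. The listed genes had also been selected for differing between these same groups. Any trend of fold change with length among such genes tends to set the groups' slopes apart. Rho and the slopes therefore describe the listed genes and need not hold for all expressed genes.

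GU-rich and AU-rich sequences have been described as binding sites of RBM38, and the 3′ UTRs of the called genes were searched for GUGUG and AUUUA. A 3′ UTR of at least 200 nt was available for 435 of the 504 called genes other than RBM38 (86.3%). For GUGUG the median ratio of observed to expected count was 1.98 in 248 genes that rose and 1.44 in 187 that fell, a difference of 0.545 (95% bootstrap interval 0.082 to 0.933; two-sided permutation p = 0.00583, adjusted p = 0.00583 over the 2 pentamers). The 9 other orders of the same bases had differences from -0.162 to 0.124. For AUUUA the medians were 0.68 and 0.949, a difference of -0.268 (interval -0.427 to -0.11, permutation p = 3e-05, adjusted p = 6e-05). The 9 other orders ran from -0.193 to -0.008, with a median of -0.123. Part of the AUUUA difference was therefore shared by other orders of the same bases. Median AU content of the UTRs was 54.6% in genes that rose and 59.5% in genes that fell. The expected counts already allow for each UTR's base composition, and the source of the shared part was not tested. Genes that rose and fell also differ in length, and the differences were taken again within 5 classes of length, a check added after the first differences were seen. Within classes of UTR length the GUGUG difference was 0.741 (permutation p = 0.00628, adjusted p = 0.00837 over 4 such tests) and the AUUUA difference -0.455 (permutation p = 1e-05, the smallest the permutations can give, adjusted p = 4e-05), which argues against UTR length as the source. Within classes of transcript length the AUUUA difference was -0.236 (permutation p = 0.00586, adjusted p = 0.00837), while the GUGUG difference was 0.397, from -0.336 to 1.26 in single classes (permutation p = 0.086, adjusted p = 0.086). The GUGUG ratio itself had a Spearman's rho of 0.03 with transcript length, and the difference had the same sign in 4 of the 5 classes. The difference did not pass within these classes. A link of GUGUG to higher levels under RBM38 overexpression therefore stays a hypothesis that cannot be told apart from the trend with transcript length. Binding was not measured, and the genes compared had been selected for differing.

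Levels of some genes in these libraries are unusual for MCF-7, the line they are labelled as. Over the 6 libraries COL1A1 averaged 7623, EGFR 5491, AXL 2736, NT5E 2546 and IL6 957 normalised counts, all high for that line, beside 20412 for KRT8 and 15115 for KRT18. The estrogen receptor gene ESR1 and CDKN1A were not among the 2004 listed genes, so no level is given for them here. The identity of the cells was not tested.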
